A study of Mus musculus with 20 samples.

How the data were processed

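The series measured mouse E14 embryonic stem cells, a pluripotent line, with 20 libraries in 10 groups of 2. Ribosome profiling (Ribo-Seq, the sequencing of mRNA fragments that ribosomes protect from RNase) covered 12 libraries from 3 lines that carry an epitope tag on 1 allele of a ribosomal protein gene: 3xFLAG-Rpl10a, Rps25-3xFLAG and Rpl22-3xHA. In each line, ribosomes captured through the tag by immunoprecipitation (IP) were set against all ribosomes of the lysate, pelleted through a sucrose cushion (total). RNA-seq of polysome gradient fractions covered 8 libraries from wild-type cells given a control siRNA or an Rpl10a siRNA. The heavy pool held mRNAs with at least 4 ribosomes and the light pool held all other fractions, from free ribonucleoproteins to polysomes of 2 to 3 ribosomes. Per the labels' protocols, cells received 100 µg/ml cycloheximide for 1 min before harvest. The RPL10A and RPS25 captures used anti-FLAG beads and the RPL22 capture an anti-HA antibody, with a lysis buffer that, unlike the other, listed no heparin.

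The authors deposited, for each Ribo-Seq library, RPKM values (reads scaled by transcript length and library size) per transcript, per the file headers. For each RNA-seq library they deposited values that the file headers call RPM (reads scaled by library size alone). The columns of this RPM kind summed to between 943664 and 1067209, with a geometric mean of 1000242, so they were treated as a scaled signal: the deposited signal appears to hold a further factor per library, whose source is not given in the sources used here. The submitters' processing notes name cutadapt and Bowtie2 for all libraries, STAR in addition for the RPL22 and RNA-seq libraries, and the mm10 build, without versions. Transcript filters are not given in the sources used here. In the files, the lowest of the transcripts' highest values was 5.1 RPKM in the RPL10A and RPS25 tables, 5 in the RPL22 table and 2 in the RNA-seq table, and every transcript of the RNA-seq table was also in the RPL10A table.

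Transcripts carried UCSC identifiers that the reference tables at hand did not pair with gene names (0 matched). Gene lists, bait genes and the level of Rpl10a itself were therefore not analysed here, and transcripts are given by identifier. Planned tests assumed whole counts. A search for a read step in the RNA-seq values decided nothing, as the step it chose, 0.15, takes in any value rounded to 1 decimal within 0.05, and the RPKM values were not searched, as transcript lengths were not used here. Whole counts were thus not recovered, the depth is treated as unknown and no count test was run. The tests were instead made on log2(value + 1) with limma 3.58.1 in R 4.3.3, with moderated variances and a variance trend, on all deposited transcripts. A fold change on this scale understates the change of transcripts with low values. The pseudocount of 1 and the variance trend were set after the values had been seen, with the call counts under other pseudocounts, without the trend and with a replicate term in view. Groups, comparisons, thresholds and the alternatives named below as set beforehand were set before the data were examined.

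Groups follow the sample titles, including the total libraries of the Rpl22 line, whose labels also name the anti-HA antibody. Each line's IP was compared with its own total libraries in a fit of those 4 libraries. Differences between lines were interaction contrasts in a fit of all 12 Ribo-Seq libraries over the 7605 transcripts common to the 3 tables. That fit estimated 1 spread per transcript for all lines, although the lines varied unequally. In their own fits the median SE of the IP ratio was 0.211 (RPL10A), 0.176 (RPS25) and 0.118 (RPL22). The RNA-seq contrasts came from 1 fit of 8 libraries. The polysome shift was heavy minus light with Rpl10a siRNA, minus heavy minus light with control siRNA. All tests were two-sided, and a transcript was called at a Benjamini-Hochberg adjusted p below 0.05 in limma. Sets of transcripts were tested with camera (competitive, preset correlation 0.01, and again with an estimated correlation) and fry (self-contained), adjusted over the sets of a comparison. Sets were the transcripts called in an IP, and the 200 with the highest and the 200 with the lowest moderated statistic in each IP, a size added after seeing the data because the RPL22 IP had no calls. Correlations across transcripts are descriptions, as transcripts are not independent replicates. Named transcripts were to be the most changed called ones with a mean level at or above the median and no overlap between the libraries of the 2 groups. With no gene names, 2 per direction were kept for the IPs and the shift, and none for other comparisons.

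The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicates of a group shared at most 1.53% identical values, so none was a copy of another. The fits were tested on simulated data drawn from the fitted levels and spreads, with 200 transcripts changed. At 4-fold, 67% were recovered for the RPL10A IP, 78% for the RPS25 IP, 93% for the RPL22 IP and 78% for the polysome shift. At 2-fold the shares were 13%, 42%, 82% and 40%. Alternatives set beforehand were library totals, a test against a 1.5-fold change, a replicate block, other sets of libraries in the fit, stricter lists, an estimated correlation and each library left out in turn. Added after seeing the data were pseudocounts of 0.1 and 5, a mean value of at least 10, aligned medians, no variance trend, the common transcripts alone and the lists of 200. The tables of the lines were normalized separately.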

Results

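The data comprised footprint densities of 8505, 8779 and 8588 transcripts in the RPL10A, RPS25 and RPL22 lines, with 2 total and 2 IP libraries each, and RNA-seq values of 8084 transcripts in light and heavy polysome fractions, with 2 libraries for each fraction and siRNA. Values of a Ribo-Seq library summed to between 1082511 and 1201737 RPKM, and the median transcript lay between 23.7 and 25.4 RPKM. Read depth is unknown, as the deposited values hold no counts. Pearson correlations between the 2 replicates of a group, on log2 values, ran from 0.973 for the RPS25 IP to 0.995 for the total libraries of the Rpl22 line.

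The first question of the design was which mRNAs are over- or under-represented on ribosomes that contain RPL10A, a protein of the large ribosomal subunit. Relative to total ribosomes of the same line, 72 transcripts had more footprints in the RPL10A IP and 52 had fewer, of 8505 tested (limma, adjusted p below 0.05). The higher transcripts had a median log2 ratio of 1.30 and the lower ones of −1.30, so a typical called transcript differed by more than 2-fold. Called transcripts were spread over the abundance range, with 20 in the lowest quintile of mean level and 30 in the highest.

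Among called transcripts at or above the median level, uc007fhi.1 rose most, from 15.8 ± 2.33 RPKM in total libraries to 86.2 ± 29.2 in IP libraries (SD, n = 2 each; log2 ratio 2.34, SE 0.25, limma adjusted p = 0.00451). uc007hnk.2 rose from 690 ± 369 to 2794 ± 94.4 RPKM (log2 ratio 2.13, SE 0.30, limma adjusted p = 0.0182). In the other direction, uc009vfb.1 fell by 2.91 on the log2 scale, from 624 ± 23.8 to 82.2 ± 6.15 RPKM (SE 0.15, limma adjusted p = 6.38e-05). uc029sdt.2 fell by 1.57, from 219 ± 19.9 to 72.9 ± 2.33 RPKM (SE 0.16, limma adjusted p = 0.00451). The 2 total libraries of uc007hnk.2 stood at 430 and 951 RPKM, so its ratio depends on which of them is used. In the RPS25 and RPL22 IPs, uc007hnk.2 also had ratios above 0 (1.04 and 0.40) and uc029sdt.2 ratios below 0 (−1.01 and −0.84), without being called there. Their directions were thus not particular to the RPL10A IP. All 124 called transcripts had non-overlapping groups, which a call with 2 libraries per group nearly requires, so this adds no support for the calls. Over all transcripts in this table the share was 56.7%, with 33.3% by chance.

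**Figure D1:**
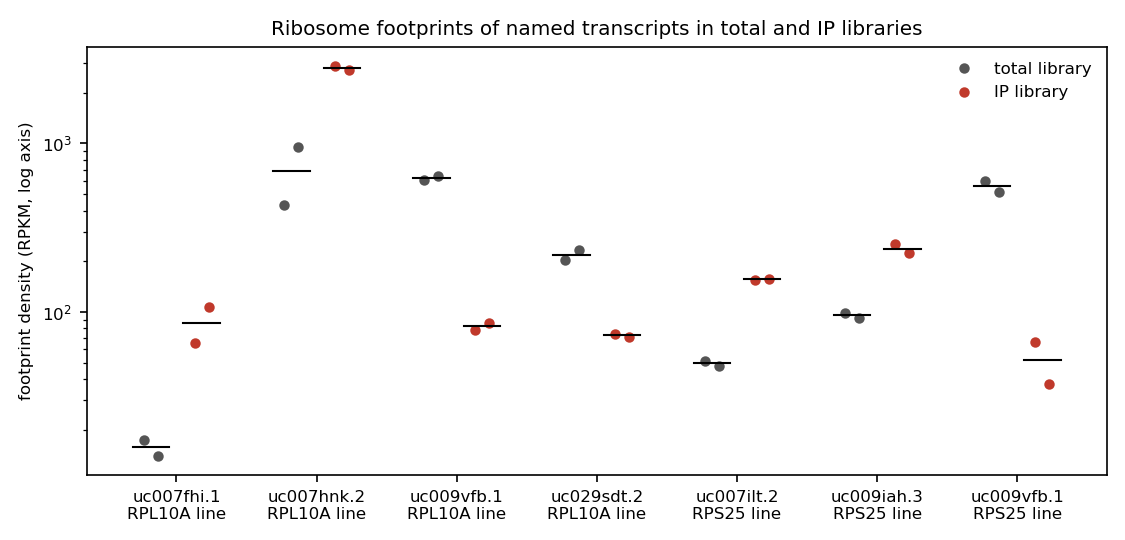
Footprint density (RPKM, log axis) of the transcripts named for the RPL10A and RPS25 captures. Grey points are total libraries, red points IP libraries and black bars the means of 2 libraries. uc009vfb.1 stood at 624 RPKM in total and 82.2 in IP libraries of the RPL10A line, and at 559 and 51.9 in the RPS25 line.

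Without any 1 of the 4 libraries, which leaves a group of 1 and less power, limma called 0 transcripts in the RPL10A IP. The log2 ratio of uc009vfb.1 then ran from −2.99 to −2.83, that of uc029sdt.2 from −1.66 to −1.48 and that of uc007hnk.2 from 1.55 to 2.70. Without a variance trend 38 were called, and 6 passed a test against a 1.5-fold change. A fit of all 12 Ribo-Seq libraries over the 7605 transcripts common to the lines called 577 higher and 725 lower. That fit applies 1 spread to lines of unequal spread.

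For RPS25, a protein of the small subunit, the IP differed from total ribosomes in 4 of 8779 transcripts, 3 higher and 1 lower (limma, adjusted p below 0.05). uc007ilt.2 rose from 49.7 ± 2.26 to 156 ± 2.47 RPKM (SD, n = 2 each; log2 ratio 1.63, SE 0.11, limma adjusted p = 0.0200) and uc009iah.3 from 95.6 ± 5.37 to 237 ± 21.0 RPKM (log2 ratio 1.30, SE 0.11, limma adjusted p = 0.0366). As in the RPL10A IP, uc009vfb.1 fell by 3.46 on the log2 scale, from 559 ± 58.8 to 51.9 ± 20.4 RPKM (SE 0.25, limma adjusted p = 0.0200). At an unadjusted p below 0.05, 1832 transcripts stood out, with 439 expected by chance, so the small number of calls does not describe the extent of the differences. No call was left without a variance trend or in a test against a 1.5-fold change, and 1 was called without the second total library and 0 without any other, while a fit of all 12 libraries over the common transcripts called 120 higher and 79 lower. The common transcripts held 2 of the 4 calls, and a fit of the 4 libraries over them called 2. With single libraries left out, the ratio of uc007ilt.2 stayed between 1.59 and 1.68.

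For RPL22, a large-subunit protein that served as a further capture, no transcript of 8588 passed (limma, smallest adjusted p = 0.105). The labels of this line's total libraries also name the anti-HA antibody, although their titles call them total: were they captures, the 0 calls and the narrow ratios would not compare captured with all ribosomes. At an unadjusted p below 0.05, 1734 did, with 429 expected by chance. Ratios spanned a narrower range than in the other lines: their SD across transcripts was 0.22 on the log2 scale, against 0.46 for RPL10A and 0.37 for RPS25. The simulated 2-fold changes were recovered for 82% of transcripts in this line, more than in the others. A fit with a replicate block, an alternative set beforehand, called 692 transcripts, so the 0 calls depend on leaving that term out. Replicate numbers were not taken to pair samples, so which of these counts holds stays open. uc009vfb.1 had the lowest ratio here too, −2.81 (SE 0.64, limma adjusted p = 0.116), with 423 ± 48.1 RPKM in total and 87.4 ± 91.6 in IP libraries (SD, n = 2 each).

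The next comparison asked how alike the 3 captures were. Transcripts that were over-represented in the RPL10A IP tended to be so in the RPS25 IP: log2 ratios correlated across 8090 transcripts with r = 0.54 (Spearman rho 0.54), and 70.4% had the same sign. Taken from single replicates, the correlation between these lines ran from 0.338 to 0.500, and that between the replicates of a line was 0.51 for RPL10A and 0.37 for RPS25 (0.53 and 0.37 with the numbers crossed). Ratios of RPL10A and RPL22 had r = −0.01 across 7840 transcripts, and those of RPS25 and RPL22 had r = −0.05 across 8049, while the 2 replicate ratios of RPL22 correlated with r = 0.47 by number and 0.29 crossed. The correlation of RPL10A with RPS25 was lowest, at 0.38, without the first RPS25 IP library.

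**Figure D2:**
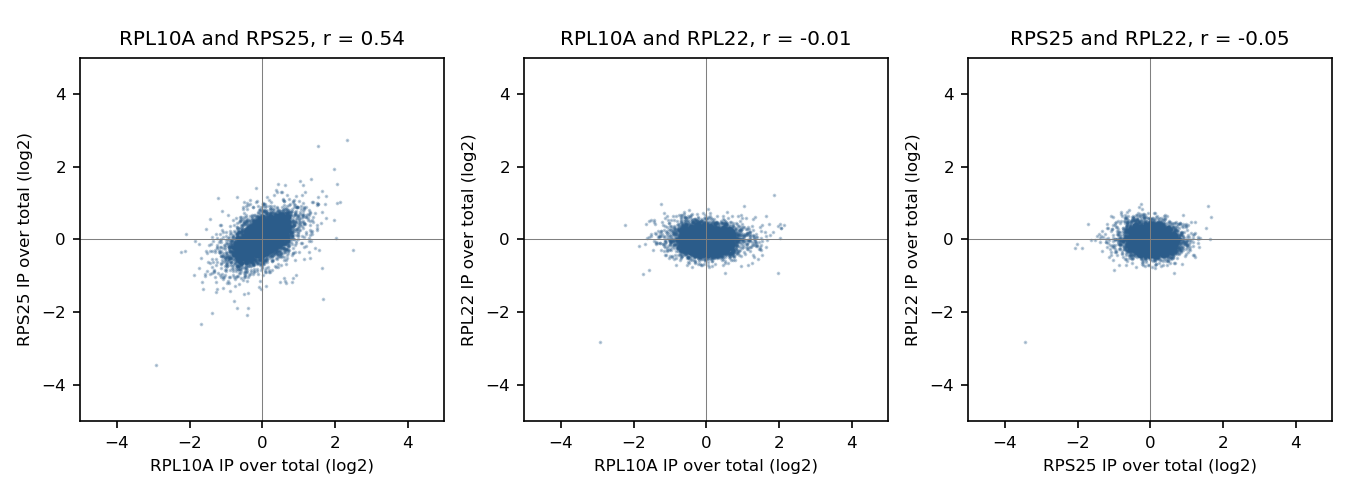
IP over total log2 ratios of each transcript (points) in pairs of lines, each axis the mean of 2 IP minus the mean of 2 total libraries on the log2(RPKM + 1) scale. RPL10A and RPS25 ratios rose together (r = 0.54), while neither followed RPL22 (r = −0.01 and −0.05).

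As a set, the transcripts called higher in the RPL10A IP had a median log2 ratio of 0.62 in the RPS25 IP, and 49 of the 54 measured there were above 0 (camera, adjusted p = 7.99e-17, and adjusted p = 0.0740 with an estimated correlation). Those called lower had a median of −0.44, with 40 of 45 below 0 (camera, adjusted p = 6.32e-11, and adjusted p = 0.199 with an estimated correlation). In the RPL22 IP the same sets had medians of 0.02 and 0.06 (camera, adjusted p = 0.212 for both).

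Testing the difference between lines directly, the RPL10A ratio exceeded the RPL22 ratio in 64 of 7605 transcripts and lay below it in 113 (limma, adjusted p below 0.05), while scaling to library totals gave 82 and 89. RPL10A and RPS25 ratios differed in 5 transcripts, 1 higher and 4 lower in RPL10A, or 1 and 1 with library medians aligned. RPS25 and RPL22 ratios differed in 2, both higher in RPS25, but in 76 higher and 12 lower after scaling to library totals. The tables of the lines were normalized separately, and antibody, buffer and line changed together between RPL22 and the others, so these contrasts compare whole procedures. Without single libraries the count for RPL10A against RPL22 ranged from 0 to 727, that for RPL10A against RPS25 from 0 to 32 and that for RPS25 against RPL22 from 0 to 156.

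The RNA-seq arm asked how mRNAs move between light and heavy polysome fractions when Rpl10a is knocked down. With control siRNA, 2266 of 8084 transcripts were higher in the heavy fractions and 2134 higher in the light fractions (limma, adjusted p below 0.05), with median log2 differences of 0.86 and −0.84. Which side held more depended on the scaling, as library totals gave 2093 on the heavy and 2258 on the light side. Abundant transcripts leaned to the heavy side: the median difference was −0.23 in the lowest quintile of mean level and 0.26 in the highest. The level of Rpl10a mRNA was not analysed here, so the strength of the knockdown was not checked.

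With Rpl10a siRNA, 4000 transcripts changed in the heavy fractions, 2164 higher and 1836 lower, and 495 changed in the light fractions, 203 higher and 292 lower (limma, adjusted p below 0.05). Fits of the 4 libraries of each fraction alone called 2842 in heavy and 749 in light fractions. The changes in the fractions correlated across transcripts with r = 0.52 (Spearman rho 0.48). Of the transcripts called in both, 113 rose and 212 fell in both, against 54.3 and 66.3 for independent lists, while 3 rose in heavy and fell in light fractions and 26 did the reverse. In the heavy fractions the lowest quintile of mean level had a median change of 0.17 and the highest of −0.30. Directions depended on the scaling: aligned medians gave 1687 higher and 2473 lower in heavy fractions, and library totals 2454 and 1243. In light fractions library totals gave 356 higher and 241 lower. Library totals moved the median change in heavy fractions by 0.11. In the light fractions no transcript was called without either control light library, either control heavy library or the second Rpl10a light library, 90 were without the first Rpl10a light library, and 987 or 978 were without the first or second Rpl10a heavy library. In the heavy fractions, 1500 were called without the second control heavy library and 2561 without the first Rpl10a heavy library.

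The polysome shift compares the heavy-against-light distribution between siRNAs. It was called for 520 transcripts, 231 shifted toward the heavy fractions and 289 toward the light ones (limma, adjusted p below 0.05). Values were scaled within each library, so a shift is relative to the other transcripts of a pool. Absolute amounts moved between fractions were not measured. uc009qun.1 had the largest rise among named transcripts (log2 shift 1.38, SE 0.21, limma adjusted p = 0.0310): with control siRNA it stood at 10226 ± 536 in light and 4600 ± 6.29 in heavy fractions, and with Rpl10a siRNA at 9614 ± 844 and 11330 ± 1808 (deposited RPM values, SD, n = 2 each). uc009ama.1 followed (log2 shift 1.25, SE 0.19, limma adjusted p = 0.0310), its light-fraction value falling from 355 ± 16.1 to 178 ± 13.5 while the heavy value went from 57.5 ± 0.354 to 69.1 ± 10.3 (SD, n = 2 each). Among called transcripts at or above the median level whose groups did not overlap, uc007prj.1 and uc007puu.1 moved most toward the light side, with log2 shifts of −1.40 each (SE 0.22 and 0.23, limma adjusted p = 0.0310 for both). uc007prj.1 went from 1216 ± 158 to 712 ± 110 in heavy fractions and from 451 ± 9.55 to 699 ± 96.0 in light ones (SD, n = 2 each), and uc007puu.1 from 993 ± 68.9 to 594 ± 115 and from 372 ± 4.67 to 586 ± 86.4.

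The median shift of all transcripts was 0.09, and with medians aligned the split became 112 toward heavy and 412 toward light. A fit with a replicate block called 2520 transcripts, 1463 toward heavy and 1057 toward light, so the more frequent direction turned. With siRNA and replicate as the block, 2980 were called, 1801 toward heavy and 1179 toward light. Light and heavy pools are parts of a gradient, so same-numbered pools of an siRNA may come from 1 gradient. Their same-numbered deviations correlated with r = 0.526 (control) and 0.621 (Rpl10a siRNA). No label ties a number to a culture or day, so replicate numbers were not taken to pair samples, and which split holds stays open. No transcript was called without a variance trend, in a test against a 1.5-fold change, or without any 1 library other than the second Rpl10a heavy library, without which 2070 were called. With single libraries left out, the shift of uc009qun.1 ran from 1.22 to 1.55 and that of uc007prj.1 from −1.56 to −1.24.

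The shifts ran against the control distribution. Of the 2266 transcripts on the heavy side with control siRNA, 78.6% had a shift below 0 (median −0.34; 284 called lower and 11 higher). Of the 2134 on the light side, 22.6% did (median 0.28; 124 called higher and 0 lower). The shift and the control contrast both use the control libraries, and unchanged groups simulated against them gave 56.1% and 42.1% below 0 for the called heavy and light sides, with medians of −0.03 and 0.05. Over all 8084 transcripts, called or not, 62.5% of those on the control heavy side shifted toward light and 73.3% of those on the control light side toward heavy. The covariance of the shift with the control contrast was −0.214, against −0.0378 in the simulation, and −0.136 and −0.271 when the quantities were taken from different replicates. The SD of the heavy-against-light contrast across transcripts was 0.81 with control and 0.68 with Rpl10a siRNA, and the contrasts correlated with r = 0.80 (Spearman rho 0.77).

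**Figure D3:**
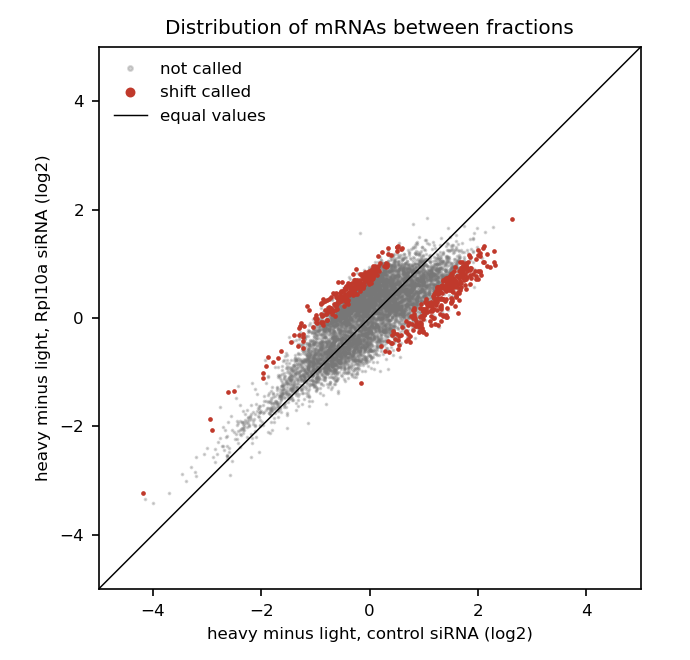
Heavy minus light log2 difference of each transcript (points) with control siRNA (x axis) and Rpl10a siRNA (y axis), each from 2 libraries per fraction. Red points are the 520 transcripts with a called shift, and the line marks equal values. Transcripts on the heavy side with control siRNA lay mostly below the line, and those on the light side mostly above it.

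The last comparison asked whether mRNAs enriched on RPL10A ribosomes moved between fractions on knockdown of Rpl10a. The transcripts called higher in the RPL10A IP had a median shift of −0.16, against 0.09 for the others, and 40 of the 66 measured were below 0 (camera, adjusted p = 0.0375). With an estimated correlation the adjusted p was 0.713. Tested against no shift rather than against the other transcripts, the set gave an adjusted p of 0.525 (fry). Of these 66 transcripts 2 were called toward the light side and 0 toward the heavy side, against 289 and 231 of all 8084. Independent lists would give 1.89 on the heavy side. Neither count exceeds the share over all transcripts. The transcripts called lower in the RPL10A IP had a median shift of 0.37, with 26 of 41 above 0 (camera, adjusted p = 0.475). Their spread was wide, with quartiles of −0.22 and 0.63, and their difference of 0.285 from the other transcripts fell to 0.0563 without the first Rpl10a heavy library, 0.0762 without the second control heavy library, 0.0948 without the first control light library and 0.102 without the second Rpl10a light library. Without the second control heavy library or the first Rpl10a heavy library, the difference of the higher set from the others shrank from −0.248 to −0.141 and −0.133, and camera's unadjusted p rose to 0.0636 and 0.0892.

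**Figure D4:**
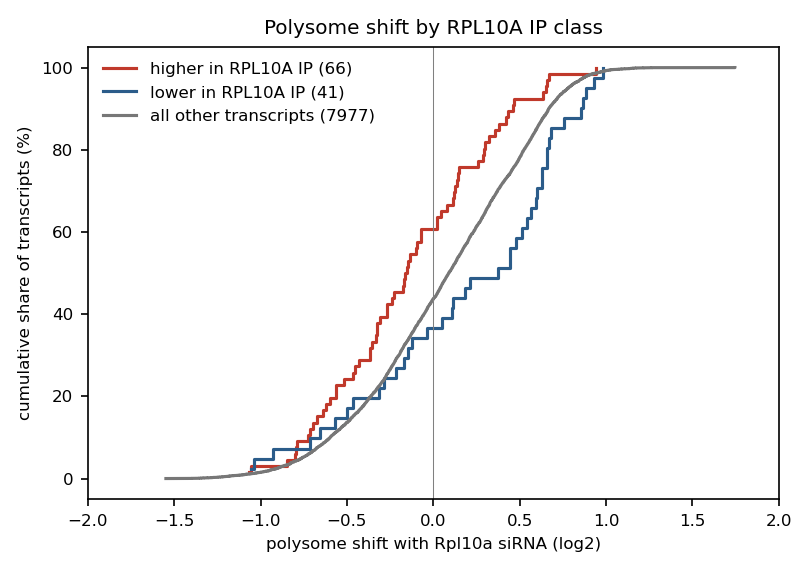
Cumulative share of transcripts (%) by polysome shift (log2) for the 66 transcripts higher and the 41 lower in the RPL10A IP and for all others. The curve of the higher set lies to the left (median −0.16, others 0.09) and that of the lower set mostly to the right (median 0.37).

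Across all transcripts, the RPL10A ratio and the shift had r = −0.03 (8084 transcripts), RPS25 had r = 0.02 (7704) and RPL22 had r = −0.20 (7489). Among the comparators, the 200 transcripts with the highest RPL22 statistic had a median shift of −0.23 over 169 measured (camera, adjusted p = 7.79e-05, and adjusted p = 0.713 with an estimated correlation). The 200 with the lowest had a median of 0.28 over 177 (camera, adjusted p = 0.0543). Neither list was adjusted for level, although the median shift was 0.18 in the lowest quintile of mean level and −0.13 in the highest. The corresponding RPS25 lists had medians of 0.12 and −0.04 (camera, adjusted p = 0.973 and 0.475), and those of RPL10A had medians of −0.11 and 0.09 (camera, adjusted p = 0.0342 and 0.973, and adjusted p = 0.713 for the first with an estimated correlation).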

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

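The tests on a capture step common to all lines, on anti-FLAG capture or batch and on mixing of fractions were chosen after the result they bear on was seen, and the estimated correlation, set beforehand, was read as a test of covarying transcripts only then. Effects under the same contrast differed between groups by an interaction test in 4 cases. The IP effect differed between RPL10A and RPS25 in 5 transcripts, between RPL10A and RPL22 in 177, and between RPS25 and RPL22 in 2. The effect of Rpl10a siRNA differed between heavy and light fractions in 520.

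The pattern weighed for the captures is the correlation of RPL10A with RPS25 ratios. After a trend on mean level was removed from each, r was 0.531, and with any 1 library left out it stayed at or above 0.385, which argues against abundance or a single library as the whole source. A step shared by all captures, such as beads against a sucrose cushion, would also tie RPL22 to RPL10A, and there r was −0.0132, but it stays open, as the labels of the Rpl22 total libraries name the anti-HA antibody and the RPL22 replicate ratios correlated with r = 0.294 with the numbers crossed. Anti-FLAG capture, or a batch shared by these lines, cannot be told apart from a shared set of mRNAs at r = 0.537, because no anti-FLAG capture from untagged cells and no capture of RPL10A or RPS25 with another antibody was used here. A shared pool of mRNAs on ribosomes holding either protein may also contribute, and is untested.

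The heavy-against-light contrast was narrower with Rpl10a siRNA. Estimated from covariances between replicates, which leave out independent errors, the SD was 0.830 times that with control siRNA (bootstrap 0.819 to 0.839). Among transcripts above the median level it was 0.825 times, so independent errors or rare transcripts do not account for the narrowing. Single replicates gave SDs of 0.849 and 0.798 with control and 0.730 and 0.669 with Rpl10a siRNA. With 2 libraries per group the bootstrap does not measure the spread between libraries, so a chance difference between them is not excluded. Light material mixed into the heavy pool could narrow the contrast, and the changes it would bring at 50% correlated with those seen by r = 0.173. This decides nothing: unchanged groups simulated against the same control libraries gave 0.119, and predictions and changes from different control heavy libraries gave 0.0470 and 0.205. Mixing and a redistribution of mRNAs on loss of RPL10A, the biological candidate, both stay open.

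The transcripts higher in the RPL10A IP had a lower polysome shift than the others. A fit for the narrower contrast did not remove it: after a fit on the mean heavy-minus-light value the difference in medians was −0.291 (bootstrap −0.429 to −0.120). After a fit on mean level it was −0.246 (bootstrap −0.338 to −0.0513), which argues against abundance as the whole cause, while a partial share stays open. Here too the bootstraps do not measure the spread between libraries. With single libraries left out, the difference without such fits ran from −0.322 to −0.133. With an estimated correlation between transcripts camera gave p = 0.299, so a few groups of covarying transcripts counted as independent may be enough to produce the call. A dependence of these mRNAs on RPL10A remains a hypothesis that these data do not settle. The 200 transcripts with the highest RPL22 statistic differed from the others by −0.329 in the shift, and the 200 for RPS25 by 0.0313. Before any such fit, a lower shift was thus not particular to the RPL10A IP. The lists are unlike, however. With control siRNA the RPL22 list leaned to the heavy side (median 0.156, others −0.0453) and the RPL10A set to the light side (−0.215). The RPL22 list was not refitted on contrast or level, so whether the remaining difference is particular to the RPL10A IP stays open.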

How the results depend on the processing

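Aligned medians, other pseudocounts, a mean value of at least 10, no variance trend, the common transcripts alone and the lists of 200 were chosen after seeing the data. Against the main counts of 124 (RPL10A), 4 (RPS25) and 0 (RPL22) for the IPs, 5 (RPL10A minus RPS25), 177 (RPL10A minus RPL22) and 2 (RPS25 minus RPL22) for the differences, 520 for the polysome shift, 4000 and 495 for the knockdown in heavy and light fractions and 4400 for heavy against light, the counts below include all that moved by over 1.5 times under these alternatives, and unless stated the cause was not tested. Without a variance trend the counts were 38 for RPL10A, 0 for RPS25, 3, 11 and 1 for the differences, 0 for the shift and 260 for the light fractions. A test against a 1.5-fold change, stricter by construction, left 6 for RPL10A, 0 for RPS25, 0 for each difference, 0 for the shift, 14 in heavy and 0 in light fractions, and 1464 for heavy against light. A mean value of at least 10 gave 190 for RPL10A and 5 for RPS25 minus RPL22, a pseudocount of 5 gave 5 for the latter, library totals gave 88 for it, and aligned medians gave 2 for RPL10A minus RPS25. A fit of all 12 Ribo-Seq libraries holds only the 7605 common transcripts and estimates 1 spread from more samples, shared by lines of unequal spread. It gave 1302 for RPL10A and 199 for RPS25, and may understate the error of the RPL10A ratio. It kept 82 of the 85 RPL10A calls and 2 of the 2 RPS25 calls among the common transcripts. Those transcripts alone, in the fits of 4 libraries, gave 93 and 2. The 4 light libraries alone gave 749. Replicate numbers are shared across groups, but with 2 numbers and no statement of a shared day they were not taken to pair samples. Same-numbered deviations correlated with r = −0.00356, 0.00774 and 0.176 in the RPL10A, RPS25 and RPL22 lines and 0.403 to 0.622 between RNA-seq groups. A replicate block gave 202, 6 and 692 calls for the RPL10A, RPS25 and RPL22 IPs, 2, 64 and 0 for the differences, 2520 for the shift, 1463 toward heavy and 1057 toward light (2980, 1801 and 1179 with siRNA and replicate as the block), against 231 and 289 without it, so the more frequent direction turned, and 5248 in heavy and 1912 in light fractions and 5370 for heavy against light, 2629 heavy and 2741 light against 2266 and 2134 without it. Leaving out each library in turn (fewer samples, the lone library of a group taken to vary like the others) gave 0 for RPL10A throughout, 0 to 1 for RPS25 and for RPL22, 0 to 32, 0 to 727 and 0 to 156 for the differences, 0 to 2070 for the shift, 1500 to 4258 in heavy and 0 to 987 in light fractions, and 3306 to 4808 for heavy against light. The set higher in the RPL10A IP differed from other transcripts by a median of −0.248 in the shift, with p = 0.299 under an estimated correlation, while fry, which tests the set against no shift and not against the other transcripts, gave p = 0.208. It lay between −0.322 and −0.133 with libraries left out. For the set lower in the IP the difference was 0.285, from 0.0563 to 0.448 with libraries left out, and with the lists of 200 it turned to −0.000753. The correlation of ratios ran from 0.385 to 0.545 for RPL10A with RPS25, −0.0795 to 0.0595 for RPL10A with RPL22 and −0.0810 to −0.0120 for RPS25 with RPL22 with libraries left out. Of 162 recomputed values of named transcripts, 90 stayed past the threshold, 72 did not and 0 reversed. RLE factors, the count filters, DESeq2 and offsets for length and GC content were not run, as the values are not counts and no lengths were used here, nor were the gene lists, as no names matched. Read depth is unknown, so its limit on low values could not be given.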

Other observations

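The counts over all 3 IPs, the lists of 200 and the transcripts named in this part were chosen after their values were seen. On the log2(value + 1) scale, a single transcript, uc009vfb.1, was at least 2-fold lower in all 3 IPs among 7605 common transcripts. It had the lowest ratio in each line. None was at least 2-fold higher in all 3 on that scale. uc029sdt.2 came close to the former, with log2 ratios of −1.57, −1.01 and −0.84 in the RPL10A, RPS25 and RPL22 IPs. In the RPL22 line its means were 6.95 and 3.45 RPKM, where the added 1 shrinks the ratio, so the count may depend on the pseudocount. The transcript uc007fhi.1 had the highest ratio of all in the RPS25 IP, from 4 ± 0.707 to 32.0 ± 3.32 RPKM (SD, n = 2 each; log2 ratio 2.72, SE 0.20, limma adjusted p = 0.0200), and was also called in the RPL10A IP. Its level in the RPS25 line lay below the median, so the rule for named transcripts left it out there. Total footprints of uc007hnk.2 differed between lines, with means of 690, 1536 and 15653 RPKM in the RPL10A, RPS25 and RPL22 lines. The tables were normalized separately, but the medians of the total libraries were close, between 23.7 and 25.45 RPKM. This transcript had the highest value in both Rpl22 total libraries. Its 2 total libraries stood at 430 and 951 RPKM in the RPL10A line and at 1970 and 1102 in the RPS25 line. The cause was not tested.

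Lists of 200 were also followed in the RNA-seq contrasts, where camera tests a list against the other transcripts and fry tests it against no change. In the heavy fractions with Rpl10a siRNA, the 200 with the highest RPL22 statistic had a median log2 change of −0.45 over 169 measured, 79 of them called lower and 18 higher (camera, adjusted p = 8.35e-07, adjusted p = 0.495 with an estimated correlation; fry, adjusted p = 0.0208). The 200 with the lowest had a median of 0.32 over 177, with 77 called higher and 20 lower (camera, adjusted p = 0.00561, adjusted p = 0.495 with an estimated correlation; fry, adjusted p = 0.0192). With control siRNA, the 200 with the highest RPS25 statistic had a median heavy-against-light difference of −0.37 over 154 measured, with 60 called higher in light and 22 in heavy fractions (camera, adjusted p = 0.0242, adjusted p = 0.792 with an estimated correlation; fry, adjusted p = 0.0344).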
